A study of Rattus norvegicus with 12 samples.

How the data were processed

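RNA from whole rat lung was sequenced in 12 libraries, 4 in each of 3 groups, prepared at a university genomics centre, per the labels' protocols. The deposited table holds raw read counts per gene, per the file headers, for 32883 genes with an Ensembl rat identifier and a symbol. Its further columns hold the authors' mean count of each group; the deposited means equalled the arithmetic mean of the 4 libraries in 32883 genes within 0.01, and were not used. The aligner, the counting tool, the strand setting and the genome build are not given in the sources used here, so no coordinates are printed. No check of gene length or GC content was made.

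Groups and replicate numbers came from the sample titles. Library totals ran from 11601929 to 70627239 counts, so that 3 counts, taken as the floor, correspond to 0.0425 to 0.259 CPM; this covers counting error only. Genes were kept by edgeR's filterByExpr on the 3 groups, which left 15257 genes with 99.9% of the counts and left out 17626. Counts were scaled by TMM, and 1 coefficient per group was fitted to all 12 libraries with the robust quasi-likelihood method (9 residual degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p below 0.05, and the standard error of a log2 fold change was its size divided by the square root of F. CPM use TMM-scaled library sizes. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

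Gene lists for 39 pathways and cell types, with 758 symbols of which 730 matched and 702 were tested, were written before the data were examined, as were the comparisons, the alternatives and the rule for named genes. Lists were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01, at least 5 tested members), with an estimated correlation and fry as alternatives. List symbols without a match were not analysed here, and 5 list symbols were matched through another name. Where several genes carried a symbol, the one with the highest mean log2 CPM was used.

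Named genes were, per comparison, the 5 up and 5 down with the smallest p among those past the threshold with an absolute log2 fold change of at least 1 and replicate values that do not overlap, leaving out names that are only identifiers; where fewer passed, the smallest p-values filled up. Not every gene so chosen is given. Gpx4, Slc7a11, Acsl4, Hmox1, Tfrc, Fth1, Ptgs2 and Bmpr2 were always given, as were 2 to 4 members with the smallest p of each list described; the comparison of MCT-Fer-1 with Control took these genes only. Kit, Gata2, Emcn and Prox1 were named after their values were seen, as members moving against their list. The endothelial, iron handling, ferroptosis defence, BMP and NRF2 lists in MCT-vehicle against Control, and the iron handling, circadian clock and BMP lists in MCT-Fer-1 against MCT-vehicle, were picked for fuller description after their values were seen. The monocrotaline score and the relabelling of libraries were also not among the results fixed beforehand.

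The gene test was tested on simulated counts with the means, spread and library sizes of these data and 200 changed genes. For MCT-vehicle against Control it recovered 44.8% of those changed 1.5-fold, 70.1% of those changed 2-fold and 92.4% of those changed 4-fold, with 9 calls of unchanged genes among 15123. For MCT-Fer-1 against MCT-vehicle there were 7 such calls among 15142 genes. A simulated retained share of 0.5 gave a ratio of 0.527, and of 1 a ratio of 0.983. A simulated 1.5-fold rise of the extracellular matrix list in MCT-Fer-1 was called by camera, with 0 other lists. Simulated genes were independent, so these checks do not cover correlation between genes.

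Alternatives were other size factors, no filter on low counts, DESeq2, limma voom with quality weights, fits of only the groups compared, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were thinning every library to the smallest total and leaving out MCT-vehicle 2 and Control 4. Log2 CPM of library pairs correlated at r between 0.945 and 0.982, and no pair agreed within sampling noise (smallest chi-square per degree of freedom 10.7). This speaks against repeated sequencing of 1 library, but cannot show that the libraries came from separate rats. Each library was taken as 1 replicate.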

Results

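RNA was sequenced from whole lungs of rats in 3 groups of 4 libraries. The groups were controls (Control), rats given monocrotaline and vehicle (MCT-vehicle), and rats given monocrotaline and ferrostatin-1 (MCT-Fer-1). Monocrotaline is a plant alkaloid that injures the lung vasculature and is used to model pulmonary hypertension. Ferrostatin-1 is a small molecule that blocks ferroptosis, a form of cell death driven by lipid peroxidation. All samples, controls included, carry a time of 25 days, without the day from which it counts. Vehicle or ferrostatin-1 was given for 10 days in the monocrotaline groups, and none is stated for controls. Against Control, monocrotaline and vehicle dosing therefore cannot be told apart. Below, the monocrotaline effect, genes and score stand for both together. The sample descriptions number the control libraries in a separate range. Whether controls were handled apart from the other rats was not tested, and such a difference would be part of this effect too. Library totals were 16640022 to 18229992 counts in Control, 13654695 to 24016262 counts in MCT-vehicle and 11601929 to 70627239 counts in MCT-Fer-1. The deepest library was MCT-Fer-1 4 and the shallowest MCT-Fer-1 1. It is not stated that each library came from a separate rat, so p-values measure the spread between these samples.

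Control and monocrotaline libraries lay apart on the first principal component of log2 CPM, which held 31.1% of the variance. Heart-muscle transcripts were high in MCT-vehicle 2 and Control 4. The tested members of the heart-muscle list summed to 464 CPM in MCT-vehicle 2, to 291 CPM in Control 4 and to 19.0 to 84.4 CPM in the other libraries. Mitochondrial transcripts took 3.27 ± 0.0864% of counts in Control, 3.97 ± 0.219% in MCT-vehicle and 3.63 ± 0.405% in MCT-Fer-1 (SD, n = 4 per group).

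**Figure D1:**
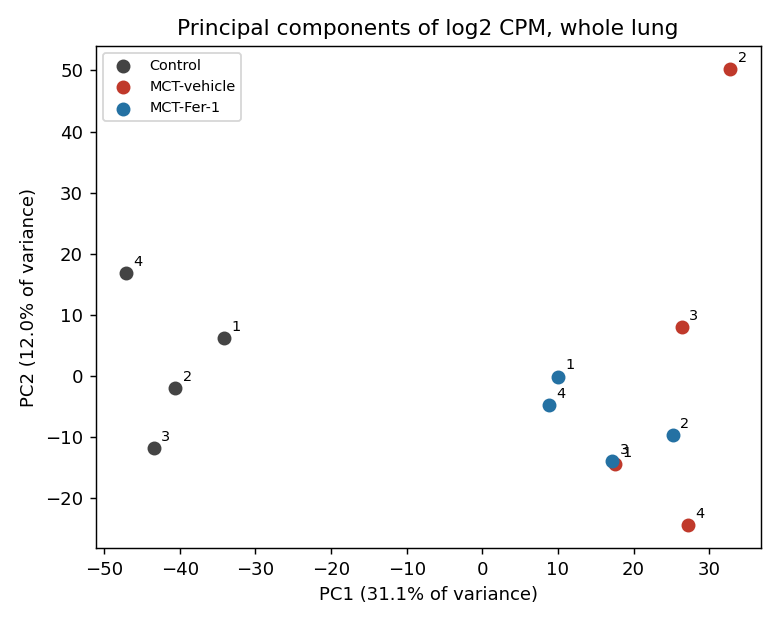
Scores of the 12 libraries on the first (x axis) and the second (y axis) principal component of log2 CPM, each point being 1 library, coloured by group and labelled with its replicate number. The 4 Control libraries lie below 0 on the first component, the 8 monocrotaline libraries above 0, and MCT-vehicle 2 stands apart on the second.

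The first comparison asked how the lungs of monocrotaline rats given vehicle differed from those of controls. Some genes of p53 signalling, complement and macrophages rose in MCT-vehicle, and some endothelial genes fell. Eda2r, a TNF receptor family member induced by p53, rose from 0.302 ± 0.0612 to 6.10 ± 1.89 CPM (SD, n = 4 per group), a log2 fold change of 4.32 ± 0.29 (SE; edgeR adjusted p = 8.60e-06). Its Control values lay near the detection floor, so the size of the rise is uncertain. C1qa, a subunit of complement C1q, rose from 30.6 ± 5.22 to 126 ± 22.5 CPM, a log2 fold change of 2.04 ± 0.14 (edgeR adjusted p = 8.60e-06). Tek, the angiopoietin receptor of endothelial cells, fell from 554 ± 25.4 to 143 ± 19.1 CPM, a log2 fold change of -1.95 ± 0.12 (edgeR adjusted p = 7.88e-06).

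Of 15257 genes tested, 1579 rose and 1264 fell (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 542 of the first and 200 of the second changed at least 2-fold. Cd80, a ligand that costimulates T cells, rose by 2.69 ± 0.20 on the log2 scale, Aen, a nuclease induced by p53, by 1.67 ± 0.13 and Rps27l by 1.11 ± 0.09. Among genes that fell, the calcium pump gene Atp2a3 had a log2 fold change of -1.28 ± 0.08, the endothelial gene Clec14a of -1.83 ± 0.14, the cytokine receptor gene Lifr of -1.54 ± 0.13 and Ushbp1 of -1.03 ± 0.09. The edgeR adjusted p of these 7 genes ran from 7.88e-06 for Atp2a3 to 3.42e-05 for Ushbp1. By the rule for named genes they were chosen among genes whose 4 values of each group did not overlap. Such separation was seen in 21.5% of genes tested, against 2.86% by chance. Without MCT-vehicle 2 and Control 4, which was tried after their heart-muscle transcripts were seen, 1675 genes changed. The identifiers are Eda2r (ENSRNOG00000013018), C1qa (ENSRNOG00000012807), Cd80 (ENSRNOG00000001527), Aen (ENSRNOG00000018421) and Rps27l (ENSRNOG00000050473) for the genes that rose. For those that fell they are Tek (ENSRNOG00000008587), Atp2a3 (ENSRNOG00000017912), Clec14a (ENSRNOG00000022697), Lifr (ENSRNOG00000011696) and Ushbp1 (ENSRNOG00000023485).

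Of the cell cycle genes, 26 of 28 rose and 0 fell, with 27 up and 0 down adjusted over the list alone. For the cell cycle list, camera gave adjusted p = 2.33e-22, and adjusted p = 0.126 with an estimated correlation. Mcm5, a subunit of the replicative helicase, rose by 1.25 ± 0.12 on the log2 scale, the topoisomerase gene Top2a by 1.58 ± 0.17 and Ube2c, a mitotic ubiquitin-conjugating enzyme gene, by 1.97 ± 0.22. Of the p53 targets, 13 of 22 rose and 0 fell, with 13 up and 2 down adjusted over the list alone. For the p53 target list, camera gave adjusted p = 2.35e-05, and adjusted p = 0.126 with an estimated correlation. Beside Eda2r and Aen, cyclin G1 (Ccng1) rose by 1.04 ± 0.10. Of the extracellular matrix genes, 24 of 31 rose and 0 fell, with 27 up and 0 down adjusted over the list alone. For the matrix list, camera gave adjusted p = 7.21e-15, and adjusted p = 0.126 with an estimated correlation. The gelatinase gene Mmp2 rose by 1.14 ± 0.13, the elastin crosslinking enzyme gene Loxl1 by 0.99 ± 0.11 and elastin (Eln) by 1.18 ± 0.14, from 829.9 ± 100.3 to 1879 ± 189.6 CPM.

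Of the macrophage markers, 18 of 24 rose and 0 fell, with 20 up and 0 down adjusted over the list alone. For the macrophage list, camera gave adjusted p = 7.04e-12, and adjusted p = 0.126 with an estimated correlation. After C1qa, the folate receptor gene Folr2 rose by 2.62 ± 0.25 and C1qc by 1.72 ± 0.17. Of the complement genes, 14 of 23 rose and 0 fell, with 15 up and 0 down adjusted over the list alone. For the complement list, camera gave adjusted p = 3.08e-07, and adjusted p = 0.126 with an estimated correlation. C1qb rose by 1.89 ± 0.19, and the C1q genes belong to both lists. Of the mast cell markers, 9 of 11 rose and 2 fell, with 9 up and 2 down adjusted over the list alone. For the mast cell list, camera gave adjusted p = 5.27e-05, and adjusted p = 0.267 with an estimated correlation. The chymase gene Cma1 rose from 3.25 ± 1.37 to 119.8 ± 60.7 CPM (log2 fold change 5.21 ± 0.46), carboxypeptidase A3 (Cpa3) rose by 4.20 ± 0.43 and the IgE receptor chain gene Ms4a2 by 3.22 ± 0.44. The members that fell were Kit, the stem cell factor receptor (log2 fold change -0.88 ± 0.20), and the transcription factor gene Gata2 (-1.11 ± 0.21).

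Of the cytokine and chemokine genes, 13 of 33 rose and 3 fell, with 21 up and 3 down adjusted over the list alone. For the cytokine list, camera gave adjusted p = 5.27e-05, and adjusted p = 0.267 with an estimated correlation. The alarmin gene Il33 had a log2 fold change of -0.92 ± 0.09, the lymphatic chemokine gene Ccl21 of 1.82 ± 0.27 and Cxcl3 of 0.81 ± 0.13. Of the erythroid genes, 0 of 13 rose and 10 fell, with 0 up and 12 down adjusted over the list alone. For the erythroid list, camera gave adjusted p = 6.22e-07, and adjusted p = 0.171 with an estimated correlation. Haemoglobin beta (Hbb) fell from 1621 ± 325 to 799 ± 131 CPM (log2 fold change -1.02 ± 0.22). The haem synthesis gene Alas2 changed by -1.05 ± 0.22 and Hba-a3 by -1.36 ± 0.29. Globin genes have near-identical copies between which reads can be split, so values of single copies are uncertain.

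Of the endothelial markers, 2 of 19 rose and 9 fell, with 2 up and 12 down adjusted over the list alone. For the endothelial list, camera gave adjusted p = 5.94e-05, and adjusted p = 0.336 with an estimated correlation. After Tek came the hyaluronan receptor gene Lyve1 (log2 fold change -1.09 ± 0.12) and the calcitonin receptor-like gene Calcrl (-1.44 ± 0.17). The members that rose were Emcn (log2 fold change 0.80 ± 0.14) and Prox1, a regulator of lymphatic endothelium (1.34 ± 0.26). Of the BMP and TGF-beta genes, 5 of 27 rose and 8 fell, with 6 up and 8 down adjusted over the list alone and no call for the list (camera adjusted p = 0.417). Bmpr2, the BMP receptor gene mutated in heritable pulmonary hypertension, fell from 282 ± 39.1 to 168 ± 31.4 CPM, a log2 fold change of -0.74 ± 0.15 (edgeR adjusted p = 0.00442). Inhbb, a subunit of activin, changed by -0.45 ± 0.09 and the inhibitory Smad6 by -1.32 ± 0.26.

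Genes of ferroptosis and iron bear on the treatment of the next comparison. Slc7a11, the cystine transporter that feeds glutathione synthesis, rose from 0.715 ± 0.342 to 5.38 ± 3.00 CPM, a log2 fold change of 2.90 ± 0.61 (edgeR adjusted p = 0.00633). The haem oxygenase gene Hmox1 rose from 70.2 ± 17.3 to 177 ± 53.2 CPM, a log2 fold change of 1.33 ± 0.35 (edgeR adjusted p = 0.0227). Its call was lost without Control 1 (adjusted p = 0.0581), without Control 3 (adjusted p = 0.0511), without Control 4 (adjusted p = 0.0640) and without MCT-vehicle 4 (adjusted p = 0.0615). No call was made for the lipid peroxidase gene Gpx4 (log2 fold change -0.03 ± 0.08), the fatty acid ligase gene Acsl4 (0.34 ± 0.27), the transferrin receptor gene Tfrc (0.16 ± 0.14), ferritin heavy chain Fth1 (0.08 ± 0.12) or the cyclooxygenase gene Ptgs2 (-0.19 ± 0.23). Their edgeR adjusted p ran from 0.413 for Acsl4 to 0.822 for Gpx4.

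Of the ferroptosis defence genes, 7 of 22 rose and 0 fell, with 8 up and 0 down adjusted over the list alone. For the ferroptosis defence list, camera gave adjusted p = 0.0430, and adjusted p = 0.153 with an estimated correlation. Beside Slc7a11 they included the transcription factor gene Nfe2l2 (log2 fold change 0.29 ± 0.06) and Gch1, which acts in tetrahydrobiopterin synthesis (0.58 ± 0.14). The call for ferroptosis defence was lost without Control 1 (adjusted p = 0.0692), without MCT-vehicle 3 (adjusted p = 0.0556) and with the replicate number as a block (adjusted p = 0.0583). Of the iron handling genes, 9 of 24 rose and 0 fell, with 9 up and 0 down adjusted over the list alone. For the iron handling list, camera gave adjusted p = 5.32e-04, and adjusted p = 0.126 with an estimated correlation. Ceruloplasmin (Cp) rose by 0.86 ± 0.14, lipocalin 2 (Lcn2) by 1.99 ± 0.42 and the metal transporter gene Slc39a14 by 0.67 ± 0.16. Of the NRF2 targets, 7 of 17 rose and 0 fell, with 9 up and 0 down adjusted over the list alone. For the NRF2 target list, camera gave adjusted p = 4.96e-04, and adjusted p = 0.168 with an estimated correlation. Epoxide hydrolase (Ephx1) rose by 0.70 ± 0.11, malic enzyme (Me1) by 0.47 ± 0.07 and peroxiredoxin 1 (Prdx1) by 0.37 ± 0.06.

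Camera with its preset correlation called 17 of 39 lists, 13 up and 4 down. Without MCT-vehicle 2 and Control 4 it called 18, and with an estimated correlation it called 0 in this and in each other comparison. The called lists not yet described follow. Smooth muscle had 3 up and 0 down of 15, with 4 up and 0 down adjusted over the list alone (camera adjusted p = 0.00666, and adjusted p = 0.605 with an estimated correlation). Dendritic cells had 5 up and 0 down of 13, with 7 up and 1 down adjusted over the list alone (camera adjusted p = 0.00705, and adjusted p = 0.290 with an estimated correlation). Arterial endothelium had 1 up and 4 down of 13, with 1 up and 5 down adjusted over the list alone (camera adjusted p = 0.0362, and adjusted p = 0.402 with an estimated correlation). Capillary endothelial subsets had 1 up and 4 down of 13, with 1 up and 4 down adjusted over the list alone (camera adjusted p = 0.0430, and adjusted p = 0.267 with an estimated correlation). Antigen presentation had 5 up and 0 down of 17, with 6 up and 0 down adjusted over the list alone (camera adjusted p = 0.0430, and adjusted p = 0.168 with an estimated correlation). The call for smooth muscle was lost by fry (adjusted p = 0.0806). The call for antigen presentation was lost without Control 1 (adjusted p = 0.0575), without Control 4 (adjusted p = 0.101), without MCT-vehicle 3 (adjusted p = 0.0556) and with the replicate number as a block (adjusted p = 0.0559). The call for arterial endothelium was lost without Control 1 (adjusted p = 0.0692) and without MCT-vehicle 3 (adjusted p = 0.0873). The call for capillary endothelial subsets was lost without Control 1 (adjusted p = 0.0720), without Control 3 (adjusted p = 0.0639), without MCT-vehicle 3 (adjusted p = 0.0873), without MCT-Fer-1 1 (adjusted p = 0.0517) and with the replicate number as a block (adjusted p = 0.103).

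Other lists had no call. No member passed the gene test in airway epithelium (15 tested), heart muscle (10 tested) and interferon response (27 tested). Fat and lymph node tissue had 4 up and 0 down of 11, aryl hydrocarbon receptor and xenobiotic genes had 1 up and 2 down of 11 and alveolar type 1 cells had 0 up and 1 down of 14. Alveolar type 2 cells had 0 up and 1 down of 15, B and plasma cells had 2 up and 0 down of 15 and cholesterol synthesis had 1 up and 0 down of 19. Circadian clock had 2 up and 0 down of 17, fatty acid oxidation had 1 up and 4 down of 21 and ferroptosis drivers had 3 up and 2 down of 20. Glycolysis and hypoxia had 4 up and 0 down of 20, immediate early and heat shock genes had 0 up and 1 down of 20 and inflammasome and lytic death had 4 up and 1 down of 15. Neutrophils had 2 up and 3 down of 17, oxidative phosphorylation had 2 up and 1 down of 26 and pericytes and fibroblasts had 5 up and 2 down of 18. Platelets had 1 up and 1 down of 9, T and NK cells had 1 up and 1 down of 23 and vasoactive signalling had 1 up and 6 down of 25. The median, the mean and the camera direction differed in sign for B and plasma cells, BMP and TGF-beta signalling, circadian clock and vasoactive signalling.

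**Figure D2:**
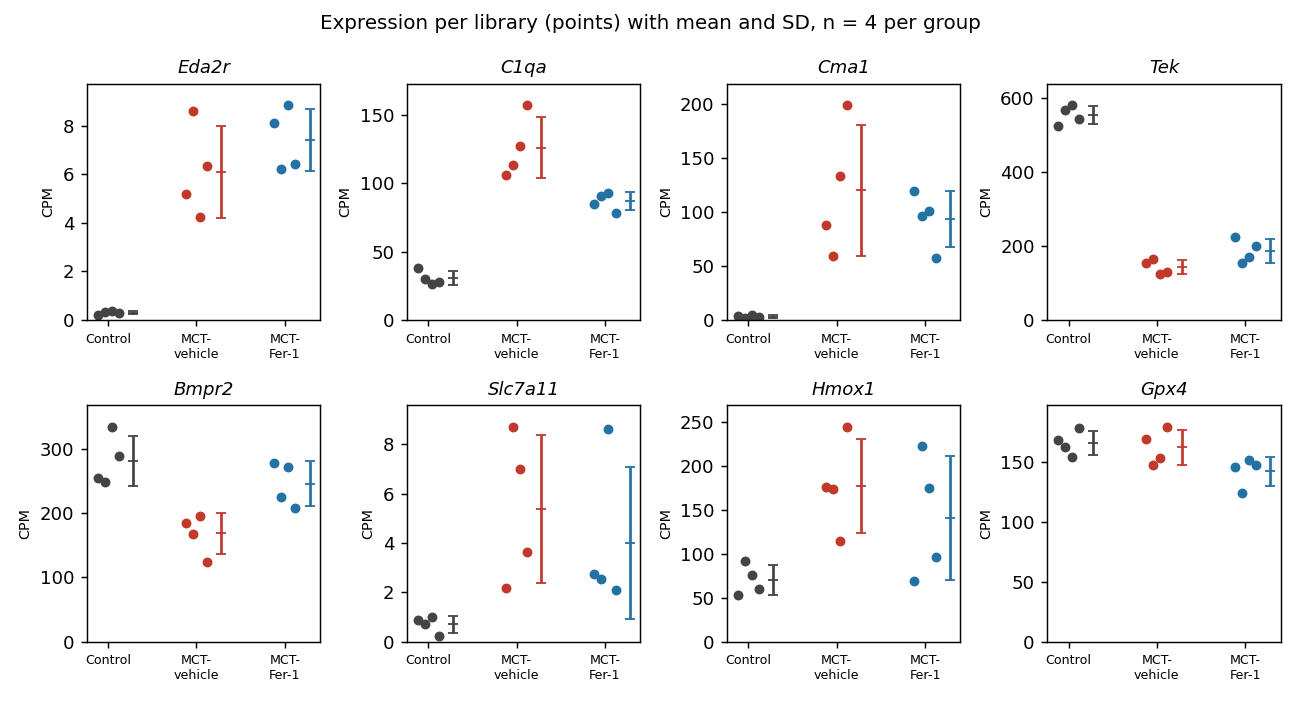
CPM of 8 named genes in each library (points), with the mean and SD of the 4 libraries of each group beside them, on y axes that start at 0 CPM. Eda2r, C1qa, Cma1, Slc7a11 and Hmox1 were higher and Tek and Bmpr2 lower in MCT-vehicle than in Control, while Gpx4 lay between 124 and 179 CPM in the 12 libraries.

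The second comparison asked how ferrostatin-1 altered the lungs of monocrotaline rats. No gene passed the threshold in MCT-Fer-1 against MCT-vehicle by edgeR, the smallest adjusted p being 0.114, so values are given without a call. Tsen34, a subunit of the tRNA splicing endonuclease, stood at 8.39 ± 2.26 CPM in MCT-vehicle and 1.59 ± 0.770 in MCT-Fer-1 (SD, n = 4 per group), a log2 fold change of -2.34 ± 0.34. Lifr stood at 225 ± 24.7 CPM in Control, 77.6 ± 12.9 in MCT-vehicle and 129 ± 17.1 in MCT-Fer-1. Bmpr2 stood at 282 ± 39.1 CPM in Control, 168 ± 31.4 in MCT-vehicle and 246 ± 34.9 in MCT-Fer-1 (log2 fold change 0.54 ± 0.15 between the last 2, edgeR adjusted p = 0.206).

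At an unadjusted p below 0.05 there were 1835 genes, 893 higher and 942 lower in MCT-Fer-1, where 5% of the genes tested make 763. Genes vary together, and the other 34 splits of these 8 libraries into groups of 4 gave 430 to 1836 such genes. The groups did not overlap in 6.10% of genes, against 2.86% by chance. The DESeq2 Wald test called 227 genes, limma voom with quality weights 0, and edgeR on these groups alone 1, AABR07018038.3. Among the genes called by DESeq2 were Bmpr2 (DESeq2 adjusted p = 0.0345), Loxl1 (0.00157), Cxcl1 (0.00171), Slc39a14 (0.00136), Calcrl (0.00871), Gch1 (0.00870) and C1qa (0.0186). Also among them were Tsen34, Dhx37, Sfn, Rcl1, Ppan, Gpbp1l1, Lifr, Tnrc6b, Tmem136, C1qc, Cfd, Col1a1, Tnc, Nfil3 and Bmpr1a. Without MCT-vehicle 3 edgeR called 41 genes, with Ppan (adjusted p = 0.00977), Tsen34, Sfn, Rcl1, Lifr, Tnrc6b, Gpbp1l1, Loxl1 and Slc39a14 among them. Without Control 2 it called 3, Tsen34 and AABR07018038.3 among them. Without MCT-Fer-1 4 it called 2, Tsen34 and RGD1562420. AABR07018038.3 and RGD1562420 were chosen after their values were seen. Without MCT-vehicle 2 and Control 4 it called 0. In simulated counts with the spread of these libraries, 200 genes were changed. The edgeR test recovered 41.8% of those changed 1.5-fold, 73.1% of those changed 2-fold and 87.9% of those changed 4-fold. The share recovered after adjustment depends on how many genes change. These shares therefore do not give the power behind the lack of calls here.

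Other genes with the smallest p, at edgeR adjusted p = 0.114 each, lay lower or higher in MCT-Fer-1. Lower were the ribosome assembly genes Dhx37 (log2 fold change -0.50 ± 0.08), Rcl1 (-0.57 ± 0.10) and Ppan (-0.66 ± 0.12), and the 14-3-3 protein gene Sfn (-1.89 ± 0.31). Higher were Gpbp1l1 (log2 fold change 0.34 ± 0.06), Lifr (0.74 ± 0.13), Tnrc6b, which acts in gene silencing by small RNAs (0.56 ± 0.10), and Tmem136 (0.66 ± 0.12). The lower genes have the identifiers Tsen34 (ENSRNOG00000055179), Dhx37 (ENSRNOG00000022171), Sfn (ENSRNOG00000033153), Rcl1 (ENSRNOG00000015491) and Ppan (ENSRNOG00000020608). The higher genes have Gpbp1l1 (ENSRNOG00000037595), Lifr (ENSRNOG00000011696), Tnrc6b (ENSRNOG00000024907) and Tmem136 (ENSRNOG00000021793). Gpx4 had a log2 fold change of -0.19 ± 0.08, Slc7a11 of -0.42 ± 0.53 (-1.13 ± 0.48 without MCT-Fer-1 3), Acsl4 of -0.15 ± 0.26 and Hmox1 of -0.33 ± 0.35. Tfrc had a log2 fold change of -0.44 ± 0.14, Fth1 0.03 ± 0.12 and Ptgs2 0.32 ± 0.23. These 7 had edgeR adjusted p from 0.268 for Tfrc to 0.945 for Fth1, and Tfrc was lower in each of the 4 MCT-Fer-1 libraries than in any MCT-vehicle library.

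Camera with its preset correlation called 8 of 39 lists, 2 higher and 6 lower in MCT-Fer-1, with 0 members past the gene test over all genes in any list. Without MCT-vehicle 2 and Control 4 it called 10, and without MCT-vehicle 1 14. The 31 extracellular matrix genes had a median log2 fold change of -0.34, with 0 up and 4 down adjusted over the list alone. For the matrix list, camera gave adjusted p = 2.77e-06, and adjusted p = 0.609 with an estimated correlation. Loxl1 had a log2 fold change of -0.56 ± 0.11. The collagen gene Col1a1 stood at 802 ± 198 CPM in MCT-vehicle and 528 ± 57.3 in MCT-Fer-1, and tenascin C (Tnc) at 247 ± 98.2 and 135 ± 26.4. The smooth muscle list had a similar median of -0.33, with 12 of 15 members lower and no call (camera adjusted p = 0.0682), and the airway list had 13 of 15 members lower (camera adjusted p = 0.639). The 24 macrophage markers had a median of -0.25, with 0 up and 4 down adjusted over the list alone. For the macrophage list, camera gave adjusted p = 0.00881, and adjusted p = 0.609 with an estimated correlation. C1qa had a log2 fold change of -0.54 ± 0.13, C1qc -0.59 ± 0.16 and the endotoxin co-receptor gene Cd14 -0.48 ± 0.14. The 23 complement genes had a median of -0.16, with 0 up and 3 down adjusted over the list alone. For the complement list, camera gave adjusted p = 0.0187, and adjusted p = 0.609 with an estimated correlation. After C1qa and C1qc came complement factor D (Cfd, log2 fold change -0.91 ± 0.26). Cfd is also on the fat and lymph node list, where the fat markers Retn (-3.86 ± 0.98) and Adipoq (-2.21 ± 0.89), named after their values were seen, were lower too. Without MCT-vehicle 2 Adipoq was at -0.13 ± 0.61, and Retn was at -3.22 ± 0.97 without MCT-vehicle 3 and at -4.93 ± 1.16 without MCT-Fer-1 3. The call for complement was lost without MCT-vehicle 2 (adjusted p = 0.114), without MCT-vehicle 3 (adjusted p = 0.0762) and without MCT-Fer-1 4 (adjusted p = 0.210). The call for macrophages was lost without MCT-vehicle 3 (adjusted p = 0.354).

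The 33 cytokine and chemokine genes had a median of -0.39, with 0 up and 1 down adjusted over the list alone. For the cytokine list, camera gave adjusted p = 0.00783, and adjusted p = 0.609 with an estimated correlation. The neutrophil chemokine gene Cxcl1 had a log2 fold change of -1.28 ± 0.29, Ccl5 0.61 ± 0.20 and Ccl20 -1.90 ± 0.62 (-1.30 ± 0.57 without MCT-vehicle 2). The 22 ferroptosis defence genes had a median of -0.08, with 0 up and 3 down adjusted over the list alone. For the ferroptosis defence list, camera gave adjusted p = 0.00881, and adjusted p = 0.252 with an estimated correlation. Of the 39 lists, fry called only this 1 (adjusted p = 0.0353). Gch1 had a log2 fold change of -0.62 ± 0.14, the glutathione synthetase gene Gss -0.34 ± 0.10 and the thioredoxin reductase gene Txnrd1 -0.27 ± 0.08. The call for cytokines and chemokines was lost without MCT-Fer-1 4 (adjusted p = 0.101). The call for ferroptosis defence was lost without MCT-Fer-1 2 (adjusted p = 0.0773).

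The 19 endothelial markers had a median of 0.07, with 4 up and 0 down adjusted over the list alone. For the endothelial list, camera gave adjusted p = 0.00881, and adjusted p = 0.653 with an estimated correlation. Calcrl had a log2 fold change of 0.70 ± 0.17, the endothelial transcription factor gene Erg 0.30 ± 0.09 and Tek 0.38 ± 0.12. The 13 erythroid genes had a median of 0.36, with 0 up and 0 down adjusted over the list alone. For the erythroid list, camera gave adjusted p = 0.00917, and adjusted p = 0.609 with an estimated correlation. Hba-a3 had a log2 fold change of 0.71 ± 0.29, Epb42 0.49 ± 0.24 and Rhag, near the detection floor at 0.217 ± 0.141 CPM in MCT-vehicle, 1.25 ± 0.68 (0.61 ± 0.61 without MCT-Fer-1 1). The 10 heart-muscle genes had a median of -2.80, with 0 up and 0 down adjusted over the list alone. For the heart-muscle list, camera gave adjusted p = 0.00881, and adjusted p = 0.653 with an estimated correlation. Ryr2 stood at 3.35 ± 3.33 CPM in MCT-vehicle and 1.02 ± 0.545 in MCT-Fer-1 and Casq2 at 5.45 ± 8.46 and 0.987 ± 0.367, with the highest values of both in MCT-vehicle 2. Their log2 fold changes were -1.69 ± 0.66 and -2.51 ± 1.02, and -0.69 ± 0.53 and -0.38 ± 0.67 without that library. Myh6 reached 104 CPM in MCT-vehicle 2. The call for endothelium was lost without MCT-vehicle 3 (adjusted p = 0.286) and without MCT-Fer-1 1 (adjusted p = 0.174). The call for erythroid cells was lost without MCT-vehicle 2 (adjusted p = 0.0572) and without MCT-Fer-1 1 (adjusted p = 0.232). The call for heart muscle was lost without MCT-vehicle 2 (adjusted p = 0.204).

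Of the lists without a call, iron handling had 0 up and 4 down adjusted over the list alone. Its members Slc39a14 and Slc11a2 had log2 fold changes of -0.81 ± 0.16 and -0.35 ± 0.10, and Hamp, which encodes hepcidin, stood at 2.94 ± 4.01 CPM in MCT-vehicle and 0.106 ± 0.119 in MCT-Fer-1, near the detection floor. Its log2 fold change of -4.74 ± 1.41 was -3.08 ± 1.24 without MCT-vehicle 2, which held 8.94 CPM, and -5.48 ± 1.71 without MCT-Fer-1 2. The circadian clock list had 4 up and 1 down adjusted over the list alone, among them Nfil3 (log2 fold change -0.73 ± 0.21), Tef (0.69 ± 0.23) and Per3 (0.78 ± 0.27). BMP and TGF-beta signalling had 2 up and 0 down adjusted over the list alone, Bmpr1a (log2 fold change 0.28 ± 0.06) and Bmpr2 (0.54 ± 0.15). Inhbb, which did not pass, was at -0.27 ± 0.09. Fat and lymph node tissue had 0 up and 2 down adjusted over the list alone. Aryl hydrocarbon receptor and xenobiotic genes had 2 up and 1 down adjusted over the list alone. Ferroptosis drivers had 1 up and 1 down adjusted over the list alone. Glycolysis and hypoxia had 0 up and 1 down adjusted over the list alone. No member passed, also adjusted over the list alone, in airway epithelium, alveolar type 1 cells, alveolar type 2 cells, antigen presentation, arterial endothelium, B and plasma cells, capillary endothelial subsets, cell cycle, cholesterol synthesis, dendritic cells, fatty acid oxidation, immediate early and heat shock genes, inflammasome and lytic death, interferon response, mast cells, neutrophils, NRF2 targets, oxidative phosphorylation, p53 targets, pericytes and fibroblasts, platelets, smooth muscle, T and NK cells and vasoactive signalling. The median, the mean and the camera direction differed in sign for alveolar type 2 cells, immediate early and heat shock genes, mast cells and vasoactive signalling.

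**Figure D3:**
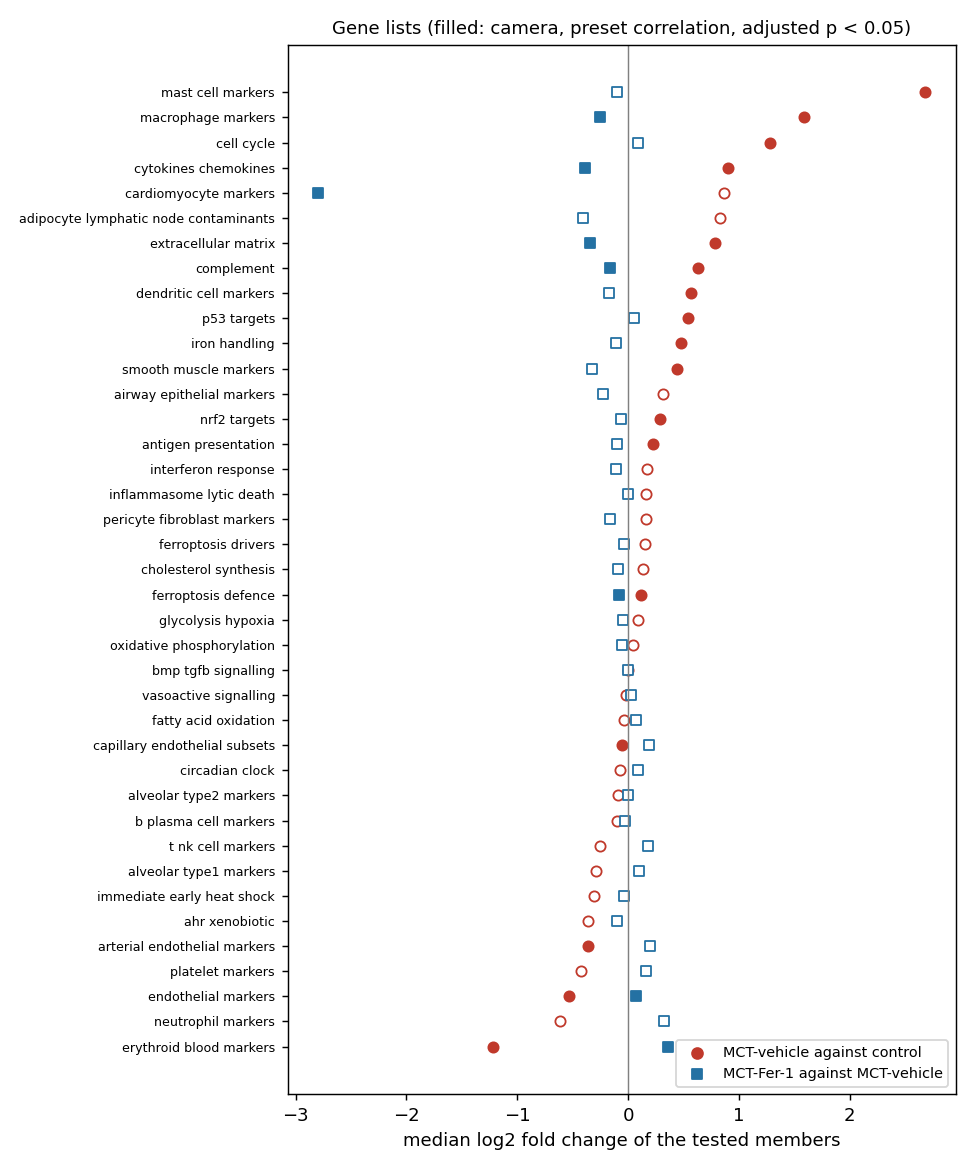
Median log2 fold change (x axis) over the tested members of each of the 39 gene lists (y axis), in MCT-vehicle against Control (circles) and MCT-Fer-1 against MCT-vehicle (squares), with filled symbols for lists that camera with the preset correlation called. Macrophage markers had medians of 1.58 in the first and -0.25 in the second comparison, and extracellular matrix genes of 0.78 and -0.34.

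The third comparison set MCT-Fer-1 against Control, which asks how far ferrostatin-1 lungs stood from control lungs. Eda2r rose to 7.40 ± 1.28 CPM from Control values near the detection floor, a log2 fold change of 4.59 ± 0.29 (edgeR adjusted p = 1.27e-05). C1qa rose to 87.0 ± 6.55 CPM (edgeR adjusted p = 6.95e-05), and Tek fell to 186 ± 31.7 CPM (log2 fold change -1.57 ± 0.12, edgeR adjusted p = 3.33e-05). Slc7a11 rose by 2.48 ± 0.61 (edgeR adjusted p = 0.0219), and its call was lost without Control 2 (adjusted p = 0.0592), without Control 4 (adjusted p = 0.0639) and without MCT-Fer-1 3 (adjusted p = 0.0619). Without MCT-Fer-1 3, which held 8.62 CPM, its log2 fold change was 1.76 ± 0.51. Hmox1 had a log2 fold change of 1.00 ± 0.35 with no call (edgeR adjusted p = 0.0972), but passed without MCT-Fer-1 1 (adjusted p = 0.0334). No call was made for Bmpr2 (log2 fold change -0.20 ± 0.15), Gpx4 (-0.22 ± 0.08), Acsl4 (0.19 ± 0.26), Tfrc (-0.28 ± 0.14), Fth1 (0.11 ± 0.12) or Ptgs2 (0.14 ± 0.23).

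Of 15257 genes tested against Control, 1017 rose and 629 fell in MCT-Fer-1 by edgeR, and 401 of the first and 100 of the second changed at least 2-fold. The total of 1646 was 978 without MCT-vehicle 2 and Control 4, 978 without Control 4 alone, 977 without MCT-Fer-1 2 and 995 without MCT-Fer-1 3. Camera called 13 lists, 10 up and 3 down, and 14 without MCT-vehicle 2 and Control 4. Cell cycle had 27 up and 0 down of 28, with 27 up and 0 down adjusted over the list alone (camera adjusted p = 7.51e-31, and adjusted p = 0.107 with an estimated correlation). Macrophages had 15 up and 0 down of 24, with 17 up and 0 down adjusted over the list alone (camera adjusted p = 3.36e-11, and adjusted p = 0.107 with an estimated correlation). Extracellular matrix had 17 up and 0 down of 31, with 21 up and 1 down adjusted over the list alone (camera adjusted p = 5.23e-11, and adjusted p = 0.244 with an estimated correlation). The p53 targets had 11 up and 0 down of 22, with 12 up and 0 down adjusted over the list alone (camera adjusted p = 8.05e-08, and adjusted p = 0.107 with an estimated correlation). Complement had 9 up and 0 down of 23, with 12 up and 0 down adjusted over the list alone (camera adjusted p = 1.14e-06, and adjusted p = 0.107 with an estimated correlation). Mast cells had 9 up and 1 down of 11, with 9 up and 1 down adjusted over the list alone (camera adjusted p = 1.36e-06, and adjusted p = 0.260 with an estimated correlation). Erythroid cells had 0 up and 4 down of 13, with 0 up and 7 down adjusted over the list alone (camera adjusted p = 5.63e-05, and adjusted p = 0.306 with an estimated correlation). Endothelium had 2 up and 8 down of 19, with 2 up and 11 down adjusted over the list alone (camera adjusted p = 0.00297, and adjusted p = 0.614 with an estimated correlation). NRF2 targets had 6 up and 0 down of 17, with 7 up and 0 down adjusted over the list alone (camera adjusted p = 0.00365, and adjusted p = 0.285 with an estimated correlation). Dendritic cells had 6 up and 0 down of 13, with 6 up and 0 down adjusted over the list alone (camera adjusted p = 0.00442, and adjusted p = 0.306 with an estimated correlation). Iron handling had 5 up and 0 down of 24, with 6 up and 0 down adjusted over the list alone (camera adjusted p = 0.00734, and adjusted p = 0.107 with an estimated correlation). Cytokines and chemokines had 7 up and 2 down of 33, with 7 up and 2 down adjusted over the list alone (camera adjusted p = 0.0278, and adjusted p = 0.674 with an estimated correlation). Arterial endothelium had 1 up and 4 down of 13, with 2 up and 4 down adjusted over the list alone (camera adjusted p = 0.0366, and adjusted p = 0.525 with an estimated correlation). The call for arterial endothelium was lost without Control 1 (adjusted p = 0.0795) and without MCT-Fer-1 4 (adjusted p = 0.114). The call for cytokines and chemokines was lost without Control 4 (adjusted p = 0.0992), without MCT-Fer-1 2 (adjusted p = 0.0719), without MCT-Fer-1 3 (adjusted p = 0.163) and by fry (adjusted p = 0.161).

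The remaining lists had no call against Control. No member passed the gene test in aryl hydrocarbon receptor and xenobiotic genes (11 tested), airway epithelium (15 tested), alveolar type 1 cells (14 tested), alveolar type 2 cells (15 tested), heart muscle (10 tested), glycolysis and hypoxia (20 tested) and oxidative phosphorylation (26 tested). Fat and lymph node tissue had 2 up and 0 down of 11, antigen presentation had 5 up and 0 down of 17 and B and plasma cells had 1 up and 0 down of 15. BMP and TGF-beta signalling had 2 up and 6 down of 27, capillary endothelial subsets had 1 up and 3 down of 13 and cholesterol synthesis had 1 up and 0 down of 19. Circadian clock had 1 up and 1 down of 17, fatty acid oxidation had 1 up and 3 down of 21 and ferroptosis defence had 1 up and 0 down of 22. Ferroptosis drivers had 0 up and 1 down of 20, immediate early and heat shock genes had 0 up and 2 down of 20 and inflammasome and lytic death had 2 up and 0 down of 15. Interferon response had 0 up and 1 down of 27, neutrophils had 2 up and 2 down of 17 and pericytes and fibroblasts had 2 up and 1 down of 18. Platelets had 1 up and 1 down of 9, smooth muscle had 1 up and 0 down of 15 and T and NK cells had 1 up and 0 down of 23. Vasoactive signalling had 2 up and 6 down of 25. The median, the mean and the camera direction differed in sign for fat and lymph node tissue, B and plasma cells, BMP and TGF-beta signalling, capillary endothelial subsets, ferroptosis drivers, oxidative phosphorylation, pericytes and fibroblasts, T and NK cells and vasoactive signalling.

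Genes called against Control were compared between the monocrotaline groups. In both comparisons 890 genes rose and 467 fell, where independent lists would share 105 and 52.1. Simulated unchanged groups against the same controls shared 0.1 and 0 on average. With the controls split 2 and 2 between the comparisons, 352 rose and 147 fell in both on average, against 25.0 and 9.76 for independent lists. The covariance of the log2 fold changes across 15257 genes, which are not independent replicates, was 0.266, against 0.0401 in the simulated unchanged groups.

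Among the 2843 genes changed in MCT-vehicle against Control, 2308 (81.2%) had the opposite sign in MCT-Fer-1 against MCT-vehicle. Both comparisons use the same vehicle libraries, and simulated groups with no ferrostatin-1 effect gave 62.2 to 65.0%. With the vehicle libraries split 2 and 2 between the comparisons, the 6 assignments gave 53.7 to 76.9%, with a mean of 65.7%. The simulations, which draw genes independently, gave 47.5 to 51.6% with such splits. Relabelling the 8 monocrotaline libraries keeps the correlation between genes, and 5 of 70 labellings, the real one included, gave a share at least as large (exact permutation p = 0.0714, one-sided). The median over the labellings was 64.9%.

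The part of the monocrotaline effect retained in MCT-Fer-1 was measured as the slope of log2 fold changes in MCT-Fer-1 on those in MCT-vehicle, each against different control libraries. The slope is 0 for values at the control level, and it can lie below 1 without any ferrostatin-1 effect, so it is read against left-out vehicle libraries. It was 0.730 over 1193 to 1851 genes, with 0.608 to 0.831 over 6 assignments of controls. With pairs of vehicle libraries on the x axis, the slope was 0.697 for MCT-Fer-1 and 0.761 for the left-out vehicle libraries, which carry no ferrostatin-1 effect, a ratio of 0.915. Over 36 assignments these slopes ran from 0.558 to 0.863 and from 0.611 to 0.979. The MCT-Fer-1 slope was the lower one in 36 of 36, but the assignments share libraries and are not independent. A monocrotaline score over 1000 genes was set to 0 at the control mean and to 1 at the mean of 3 vehicle libraries, leaving out the library scored. It was 0.916 ± 0.0827 in MCT-vehicle and 0.820 ± 0.0870 in MCT-Fer-1 (SD, n = 4 per group). The difference of -0.0962 was not larger than the spread between libraries allows (exact permutation p = 0.143, two-sided, where the smallest possible was 0.0143).

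**Figure D4:**
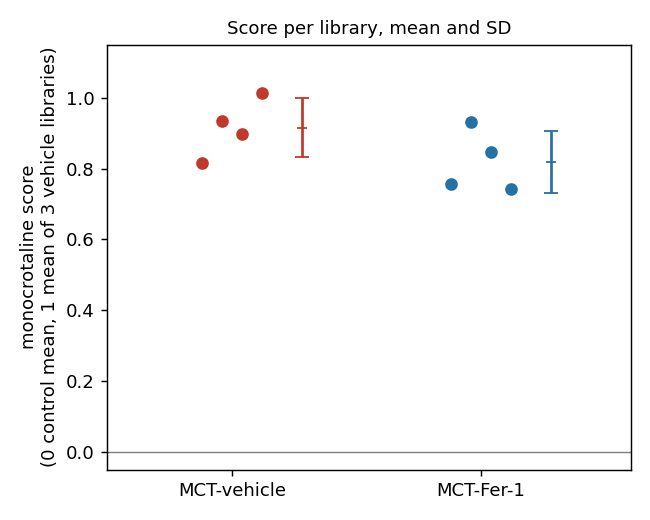
Monocrotaline score (y axis, no unit) of each library (points) in MCT-vehicle and MCT-Fer-1, with the mean and SD of 4 libraries beside them, where 0 is the control mean and 1 the mean of 3 vehicle libraries. The groups overlap, with means of 0.916 and 0.820.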

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

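The tests of the endothelial markers, the thinning of libraries, the fit without MCT-vehicle 2 and the relabelling of libraries were chosen only after the results they bear on were seen. In 252 groups of 4 values, for the named genes and 5 library measures, 26 had 1 library far from the rest by Dixon's test, where chance gives about 13. Summed heart-muscle transcripts stood apart in Control 4 (291 CPM, others 19.1 to 37.3), MCT-vehicle 2 (464 CPM, others 25.6 to 84.4) and MCT-Fer-1 2 (47.2 CPM, others 19.0 to 22.7). Among single genes this held for heart-muscle genes and Hamp: Casq2 in Control 4 (4.44 CPM, others 0.715 to 0.903), Hamp in Control 4 (3.26 CPM, others 0.0602 to 0.165), Myh6 in Control 4 (50.8 CPM, others 0 to 1.05), Casq2 in MCT-vehicle 2 (18.1 CPM, others 0.630 to 2.18), Ryr2 in MCT-vehicle 2 (8.30 CPM, others 1.11 to 2.16), Hamp in MCT-vehicle 2 (8.94 CPM, others 0.726 to 1.26) and Myh6 in MCT-vehicle 2 (104 CPM, others 0 to 9.55). Summed erythroid transcripts stood apart in Control 1 (5552 CPM, others 3391 to 3740), and ribosomal protein genes took 3.03% of counts in MCT-vehicle 4 (others 2.67 to 2.70%).

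Of the other named genes, 1 library stood apart for Ccl5 in Control 3 (98.2 CPM, others 59.7 to 62.6), Nfil3 in Control 1 (20.4 CPM, others 13.0 to 13.5), Mmp2 in Control 1 (247 CPM, others 176 to 188), Gss in Control 3 (19.2 CPM, others 16.8 to 16.9), Slc11a2 in Control 3 (55.7 CPM, others 48.8 to 49.3), Ptgs2 in MCT-vehicle 1 (7.78 CPM, others 6.12 to 6.35) and Epb42 in MCT-vehicle 3 (2.68 CPM, others 1.47 to 1.58). The same held for Ppan in MCT-vehicle 3 (24.1 CPM, others 33.9 to 35.9), Cfd in MCT-vehicle 3 (46.6 CPM, others 21.0 to 24.7), Me1 in MCT-Fer-1 3 (57.0 CPM, others 48.4 to 48.9), Slc7a11 in MCT-Fer-1 3 (8.62 CPM, others 2.10 to 2.76), Gch1 in MCT-Fer-1 3 (17.7 CPM, others 15.0 to 15.2), Ccl21 in MCT-Fer-1 2 (380.0 CPM, others 171 to 204) and Tsen34 in MCT-Fer-1 4 (2.74 CPM, others 1.12 to 1.29).

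Camera with the preset correlation called the endothelial list lower in MCT-vehicle than in Control, but not with an estimated correlation (adjusted p = 0.336), and 2 of its 19 members rose. If only endothelial cells made these transcripts, cell loss, or dilution by RNA of other cell types, would as the whole cause lower all of them alike. About 1.14 of 17 blood endothelial markers would then lie more than 2 SE from their median of -0.537. Instead 8 lay there, from Tek at -1.95 to Emcn at 0.80 (exact binomial p = 5.82e-06, one-sided, taking markers as independent and the median as exact). Whether other cell types also express the markers was not tested, and this would make the falls unequal too. A first bound, 9 markers, was not reached and was replaced after the count was seen, and a first test of dilution, the pooled median of 4 resident lists (0.0507), was dropped since smooth muscle was itself called up. Smooth muscle (median log2 fold change 0.441) and pericytes and fibroblasts (0.162) lay above 0. Alveolar type 1 (-0.293, 10 of 14 members below 0) and type 2 markers (-0.0936, 10 of 15) lay below 0, the direction of dilution. Neither alveolar list was called (camera adjusted p = 0.0702 and 0.0885). Their joint median lay 0.257 ± 0.195 (bootstrap SD) above the endothelial one. Type 1 alone lay 0.244 ± 0.196 above it and type 2 alone 0.444 ± 0.213, so type 2 markers fell less than equal dilution would give. Dilution or cell loss stays open as a part of the cause and, where other cells share the markers, as the whole. A loss of some endothelial subsets and a change of expression within the cells stay open too.

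The median log2 fold change of the extracellular matrix list in MCT-Fer-1 against MCT-vehicle was -0.341, -0.245 without MCT-vehicle 2 and -0.336 after thinning every library to the smallest total. The smooth muscle list lay lower too (median -0.329), as did the airway list (median -0.229). Pericytes and fibroblasts had a median of -0.161, with 13 of 18 members lower and no call. Another share of vessel, airway or fibroblast tissue in the libraries therefore stays open.

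The opposite direction of monocrotaline genes in MCT-Fer-1 could come from the shared vehicle libraries. With these split the share was 65.7%, above the simulated maximum of 51.6%. The simulations draw genes independently and so understate chance. Of 70 labellings 5, the real one included, gave a share at least as large as the real 81.2%, the highest other being 88.1%. Chance is therefore not excluded, and an effect of ferrostatin-1 stays a hypothesis.

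Other splits of the 8 libraries of a comparison show where chance can be excluded, at best at an exact permutation p of 0.0286, the smallest possible. Each other split mixes libraries of both groups, so a real difference widens its spread. A split with 1 library of each group exchanged also keeps part of that difference, which can raise its count. Only the rank of the real split is therefore read. For genes changed in MCT-vehicle against Control, 1 of 35 splits, the real one with 2843 genes, gave as many, and the highest other gave 1. For MCT-Fer-1 against Control it was 1 of 35, with 1646 genes against 6. In MCT-Fer-1 against MCT-vehicle any split gives at least the real count of 0 genes, so 35 of 35 (highest other 1) decides nothing. There 2 gave at least the 1835 genes at an unadjusted p below 0.05 (highest other 1836), so chance is not excluded for that number. Nor is it for the counts of lists: 4, 29 and 15 of 35 splits gave at least the 17, 8 and 13 lists called in the 3 comparisons, with the highest others at 21, 23 and 18. The split with 21 lists had Control 4 and MCT-vehicle 1 exchanged and so kept part of the real difference. For lists these ranks therefore cannot tell chance from a real difference.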

How the results depend on the processing

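Thinning and leaving out MCT-vehicle 2 with Control 4 were chosen after seeing the data. Genes changed in MCT-vehicle against Control numbered 2843, and 1675 without those 2 libraries, which has fewer samples. In MCT-Fer-1 against MCT-vehicle the 0 genes became 227 by DESeq2 and 1 with only those groups in the fit; the cause was not tested. In MCT-Fer-1 against Control 1646 became 978 without the 2 libraries. With an estimated correlation, 0 lists were called in each comparison, and fry called 1 in MCT-Fer-1 against MCT-vehicle. Leaving out each library in turn gave 2021 to 2860, 0 to 41 and 977 to 1714 genes and 15 to 19, 6 to 14 and 12 to 15 lists in the 3 comparisons, and leaving out each MCT-Fer-1 library gave an opposite-sign share of 76.8 to 84.9% and a slope, with no correction for the slope of left-out vehicle libraries, of 0.695 to 0.753. The 14 lists in MCT-Fer-1 against MCT-vehicle came without MCT-vehicle 1. Among named genes, signs turned when 1 library was left out for 5 without a call, with these log2 fold changes then, Gpx4 in MCT-vehicle against Control (0.00423), Fth1 in MCT-vehicle against Control (-0.00716), Acsl4 in MCT-Fer-1 against MCT-vehicle (0.0949), Fth1 in MCT-Fer-1 against MCT-vehicle (-0.0432) and Ptgs2 in MCT-Fer-1 against Control (-0.0778). Libraries with the same replicate number in their titles did not pair: their deviations from the group means correlated at -0.0633 to 0.102, and 4 of 12 correlated best with their own number. The sample descriptions number the Control and MCT-Fer-1 libraries otherwise, and pairing by those numbers was not tested. By DESeq2, 23 results of chosen genes passed that did not by edgeR. The replicate block gave 2812, 0 and 1676 genes and 14, 8 and 13 lists. The alternatives for normalized values were not run, since the values are counts. In the other alternatives run the counts of genes and lists stayed within 1.5 times.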

Other observations

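The thinning, the fit without MCT-vehicle 2 and the gene lists in this part were chosen after the genes leading the MCT-Fer-1 against MCT-vehicle comparison had been seen, the lists from members not yet looked at. Of 60 held-out ribosome biogenesis genes, 56 were lower in MCT-Fer-1, 28 of them at an unadjusted p below 0.05 and none past adjustment over all genes, with a median log2 fold change of -0.203. Examples are Bysl (-0.41 ± 0.11), Dkc1 (-0.67 ± 0.18) and Noc4l (-0.49 ± 0.14). Of 19 held-out STAT3 targets, 16 were lower, with a median of -0.300, including Socs3 (-0.91 ± 0.25) and Osmr (-0.87 ± 0.25).

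A hypothesis is that ferrostatin-1 lowers ribosome biogenesis transcripts in monocrotaline lungs. The held-out list gave a camera p of 7.74e-16 with the preset correlation and 0.0366 with an estimated correlation. Its median was -0.209 after thinning to the smallest total and -0.219 without MCT-vehicle 2, where the estimated-correlation p was 0.0683. The held-out genes were read in the same libraries as the genes that prompted the list. They also vary together (estimated correlation 0.275), so their p-values are not independent support. However, 2 of 35 splits of the 8 libraries gave a median as far from 0, the highest other being 0.206, with MCT-vehicle 3 and MCT-Fer-1 2 exchanged, so chance is not excluded and the hypothesis may not hold. For the STAT3 targets, likewise read in the same libraries, the camera p was 3.16e-05, and 0.0594 with an estimated correlation. Library splits, thinning and the fit without MCT-vehicle 2 were not run for this list. Chance is thus not excluded there either, and that hypothesis stays open.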
